A study of Mus musculus with 15 samples.

How the data were processed

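The study used chromatin immunoprecipitation followed by sequencing (ChIP-seq) in G1E cells, a mouse erythroblast line that lacks the erythroid transcription factor GATA1. In part of the samples the cells carried GATA1-ER, a fusion of GATA1 to the ligand-binding part of the oestrogen receptor, which was switched on with 100 nM estradiol for 24 h. The labels describe 15 samples in 10 groups: GATA1 ChIP with and without the BET bromodomain inhibitor JQ1 at 250 nM, and ChIP of BRD2, BRD3 and BRD4, the BET proteins that bind acetylated chromatin, with or without active GATA1. Peak lists were at hand for 2 samples only, the GATA1 ChIP replicates treated with estradiol and no JQ1. The other 13 samples were not analysed here, so no comparison of JQ1 with control, and none of BET protein occupancy, was made.

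Per the labels, immunoprecipitation followed formaldehyde fixation and sonication, the antibody was the N6 antibody to GATA1 from a single lot, and libraries were size-selected and sequenced on an Illumina HiSeq 2000. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 1.8.4 and aligned with Bowtie 1.0.0, and the genome build was mm9. The peak caller, its settings and any input control are not given in the sources used here. Each deposited file is a broadPeak list of 1 sample, so replicates were not pooled in it. In the broadPeak layout the seventh column is the signal value. The deposited signal values ran from 3.19 to 40.39, and their scale is not stated. The next column is −log10 of the p-value, and the deposited −log10 p values start at 5.0 in both lists, so the lists hold peaks with a p of 1e-05 or smaller. The ninth column, the place of a q-value in that layout, holds the deposited value 1 in every row, and the score column holds 0, so neither was used. These values are the authors' own for each peak. They were used to describe, rank and filter peaks within a list and, for peaks found in both lists, to describe how far the lists' values agree, with no scaling between lists. Read depth is unknown from these files.

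Starts were read as zero-based, as the broadPeak layout defines them, and all coordinates are given 1-based on mm9. A reference gene table of GRCm38 was at hand. It is of another build than the mm9 lists, so no peak was assigned to a gene. In 6 of 20 chromosomes peaks ended beyond the last gene of that table, which would not show a difference of build by itself. The tests planned on positions relative to genes and on fixed gene lists were therefore not run.

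Peaks of the lists were called shared where they overlapped by at least 1 bp, and the counts were checked against bedtools 2.31.1. The shared percentage was compared with 1000 circular shifts of the replicate 2 list, each chromosome by its own random distance and with its largest peak end as its length, in a one-sided permutation test whose smallest possible p is 0.001. Signal values were compared over peaks that had exactly 1 partner in the other list, by Spearman's rho and Pearson's r of logarithms, with a 95% interval from 1000 bootstrap draws of 5 Mb blocks. These correlations run across peaks, which are not independent replicates, so they carry no p-value. Within each list, the probability that a shared peak outranks one found in that list only was computed on the signal value, with an interval from 300 draws of the same blocks. Clustering was measured as the percentage of peaks with a neighbouring peak centre within 10 kb, against 1000 uniform redistributions of the peaks within the span of each chromosome (one-sided permutation test). Percentages of peaks have exact Clopper-Pearson 95% intervals, which cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

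The named peaks were fixed by rule before the data were examined: the 10 shared peaks with the best mean rank of signal value, the 3 peaks of highest signal found in each list only, the widest shared peak, and the 5 windows of 100 kb with the most shared peaks, with ties counted. The alternatives fixed at the same time were other definitions of overlap, stronger peaks only, lists of equal length, merging of peaks within 1 kb, autosomes only, other neighbour distances, and −log10 p in place of the signal value. Limits of −log10 p of 10 or more and lists without chromosome 12 were added after seeing the data. The procedures were tested on simulated data. With 60% of 7374 simulated peaks shared, 60.2% were recovered, and a rank correlation of 0.57 was recovered where the simulated Pearson correlation of log signals was 0.6. Over 20 pairs of independent lists the shared percentage was 0.58%, against 0.54% after shifting, and 2 of the 20 pairs passed the shift test by chance.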

Results

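The deposited data analysed here are the peaks called in 2 replicate GATA1 ChIP-seq samples of G1E erythroblasts whose GATA1-ER fusion had been active for 24 h in 100 nM estradiol. GATA1 is the transcription factor that drives erythroid maturation, and G1E cells lack their own GATA1, so GATA1 occupancy in them would come from the induced fusion protein. The called peaks are termed GATA1 sites below. No peak list from cells without GATA1 or of an input was at hand, so calls not due to GATA1 cannot be told apart. The study set these samples beside cells that also received JQ1, to ask how BET bromodomain inhibition affects GATA1 binding. Only the lists without JQ1 were analysed here, and the comparison made is that between the replicates. Nothing in the labels says whether the replicates came from separate cultures, so the spread between them may be technical.

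GATA1 ChIP gave peaks over many short stretches of the genome in each sample. The replicate 1 list held 7374 peaks and the replicate 2 list 7494, on the 19 autosomes and X. Median peak width was 776 bp in replicate 1 (interquartile range 673 to 905 bp) and 832 bp in replicate 2 (727 to 957 bp). The peaks covered 6.15 Mb and 6.66 Mb of the genome. The median signal value, the authors' own measure of peak strength, was 7.61 in replicate 1 and 7.28 in replicate 2, and the median −log10 p was 8.90 and 9.11. Signal value and −log10 p ranked peaks alike within a list, with a Spearman rho across peaks of 0.80 in replicate 1 and 0.79 in replicate 2.

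Most GATA1 sites were found in both samples. Of the replicate 1 peaks, 5207 of 7374 were overlapped by a replicate 2 peak, or 70.6% (95% interval 69.6 to 71.7%), and of the replicate 2 peaks 5194 of 7494, or 69.3% (68.3 to 70.4%). Circular shifts of the replicate 2 list left a mean of 0.561% of replicate 1 peaks overlapped and at most 3.53%, so the observed overlap was 126 times the shifted one (one-sided permutation p = 0.001, the smallest that 1000 shifts allow). The shared stretches made up 49.4% of the sequence covered by either list.

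Recovery in the other sample rose with the strength of the site. In the strongest decile of the replicate 1 list, with signal values of 13.32 and above, all 737 peaks were shared (interval 99.5 to 100%). In the strongest decile of the replicate 2 list 742 of 749 were shared, or 99.1% (98.1 to 99.6%). In the weakest decile the shared percentage was 42.0% (38.4 to 45.7%) in replicate 1 and 38.0% (34.5 to 41.6%) in replicate 2. Shared peaks had a median signal value of 8.46 against 6.34 for peaks found in replicate 1 only, and 7.95 against 5.96 for those found in replicate 2 only. A shared peak outranked an unshared one with a probability of 77.9% (76.9 to 78.9%) in replicate 1 and 78.2% (77.2 to 79.2%) in replicate 2, where 50% would mean no difference. Shared peaks were also wider, with medians of 815 bp against 692 bp in replicate 1 and 872 bp against 753 bp in replicate 2. Of the peaks found in 1 list only, 9.04% in replicate 1 and 8.96% in replicate 2 lay within 1 kb of a peak in the other list.

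**Figure D1:**
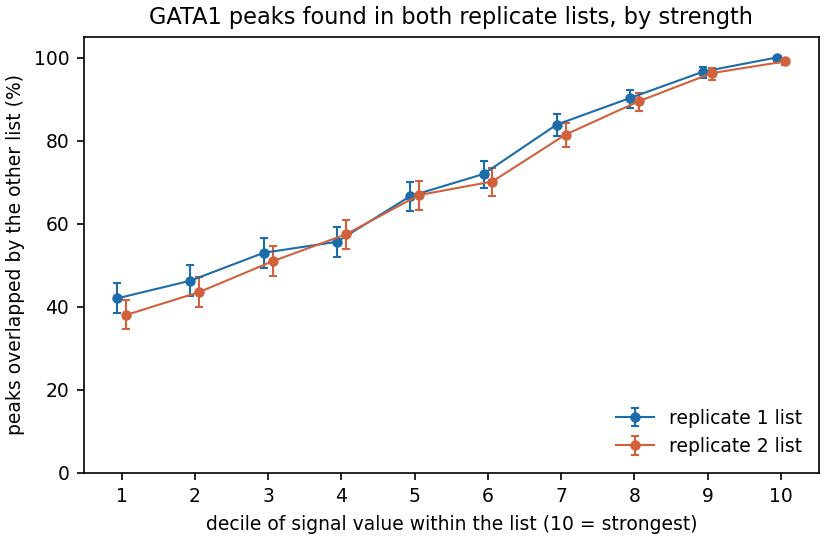
Percentage of peaks overlapped by at least 1 bp in the other replicate's list (vertical axis) for each decile of the list by signal value (horizontal axis, 10 the strongest), with exact 95% binomial intervals. Recovery rises in both lists, from 42.0% and 38.0% in the weakest decile to 100% and 99.1% in the strongest.

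The strength of shared sites was similar in the samples, with a scatter that limits what a single site can show. Over 5042 peaks with exactly 1 partner, the Spearman rho of the signal values was 0.69 (interval 0.67 to 0.71) and the Pearson r of their logarithms 0.76, both across peaks. The median ratio of replicate 2 to replicate 1 was 0.949, and the SD of the log2 ratio was 0.37. After removal of the median ratio, 89.1% of the shared peaks lay within 1.5-fold. The lists were not scaled to each other here, so the median ratio does not measure a difference in binding.

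**Figure D2:**
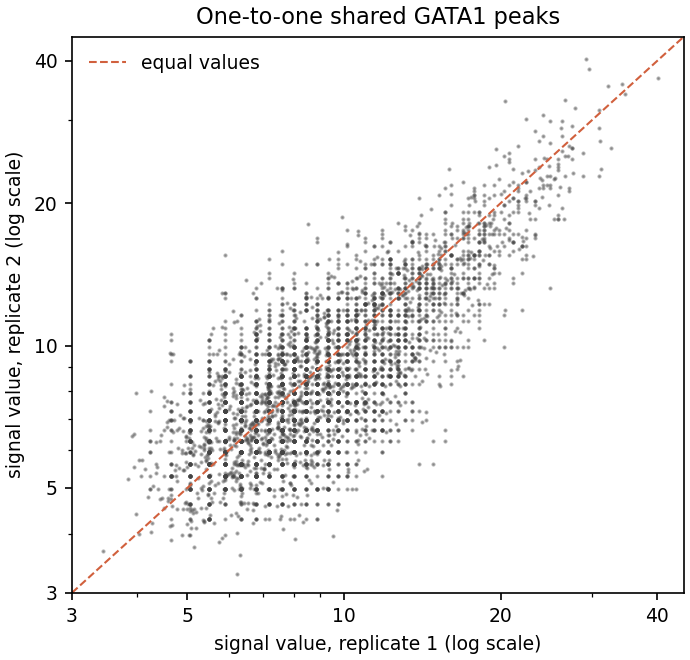
Signal value in replicate 1 (horizontal axis) and replicate 2 (vertical axis) of the 5042 one-to-one shared peaks, both on log scales, 1 point per peak, with the line of equal values. Points follow the line with a Spearman rho of 0.69, and at low values they fall on a grid, since the deposited signal values are stepped.

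The strongest shared site by mean rank of signal value lay on chromosome 11 at 104829176 to 104830267 in replicate 1, with a signal value of 38.5 ± 2.42 (SD, n = 2). It ranked 1 in replicate 1 and 3 in replicate 2. By −log10 p it was not the first, with 177.9 and 170.8 against 316.4 and 310 on chromosome 7 at 86149203 to 86151868. The next sites by mean rank were on chromosome 4 at 138728173 to 138729458 (35.0 ± 1.06, SD, n = 2), chromosome 9 at 14839486 to 14840781 (34.4 ± 0.40, SD, n = 2) and chromosome 12 at 58287086 to 58288442 (33.8 ± 2.32, SD, n = 2). A second chromosome 12 site at 106265473 to 106266465 (34.0 ± 6.22, SD, n = 2) and a chromosome 5 site at 38900498 to 38901402 (34.8 ± 7.93, SD, n = 2) differed more between samples. The chromosome 5 site ranked 1 in replicate 2 and 13 in replicate 1. A chromosome 1 site at 23539725 to 23541484 had a signal value of 31.2 ± 0.41 (SD, n = 2) and the highest −log10 p of these 10 sites, 289.9 in replicate 1 and 303.1 in replicate 2. The remaining 3 sites were on chromosome 3 at 87704913 to 87705816 (29.8 ± 2.86, SD, n = 2), chromosome 5 at 76855123 to 76856674 (29.8 ± 1.46, SD, n = 2) and chromosome 11 at 77882828 to 77883874 (29.1 ± 2.81, SD, n = 2). The widest shared peak, on chromosome 4 at 129878988 to 129886400, spanned 7413 bp in replicate 1 and 7742 bp in replicate 2. Its signal value was 16.7 ± 1.56 (SD, n = 2).

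The strongest sites seen in 1 sample only were weaker in replicate 1 than in replicate 2. In replicate 1 they lay on chromosome 11 at 59285798 to 59286597 with a signal value of 13.11, on chromosome 18 at 58814452 to 58815282 with 12.69, and on chromosome 10 at 61805245 to 61805923 with 12.69. In that list 10.1% of peaks were stronger than the first of these. In replicate 2 they lay on chromosome 10 at 117501607 to 117502653 with a signal value of 22.51, on chromosome 5 at 123210430 to 123211633 with 21.19, and on chromosome 7 at 117916733 to 117918756 with 16.22. Only 0.881% of the replicate 2 peaks were stronger than the first. Of peaks with a signal value of 15 or more, 0 of 504 in replicate 1 and 3 of 401 in replicate 2 lacked a partner.

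GATA1 sites lay closer together than evenly spread ones would. In replicate 1, 41.8% of peaks had a neighbouring peak centre within 10 kb, against a mean of 6.43% when peaks were redistributed evenly along each chromosome. In replicate 2 it was 40.4% against 6.50% (one-sided permutation p = 0.001 for each list, the smallest that 1000 redistributions allow). Even redistribution takes no account of where genes or mappable sequence lie, and neighbouring calls may be parts of 1 site. The test therefore shows only that peaks were not spread evenly. The median distance between neighbouring peaks was 42.6 kb in replicate 1 and 47.5 kb in replicate 2. Shared peaks occurred in 3081 of 25474 windows of 100 kb, or 12.1%, and 104 windows held 5 or more.

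The densest window was on chromosome 8 from 124.8 to 124.9 Mb. It held 19 peaks in replicate 1, of which 16 were shared, and 15 peaks in replicate 2. Its shared peaks were strong, with a median signal value of 12.76 in replicate 1 and 12.48 in replicate 2. On chromosome 12 from 106.2 to 106.3 Mb, 11 of 13 replicate 1 peaks were shared, among them 1 of the 10 sites above with the best mean rank of signal value. A chromosome 17 window from 15.1 to 15.2 Mb held 16 peaks in replicate 1, of which 10 were shared, and 12 in replicate 2. The median signal value of its shared peaks was 5.38 in replicate 1 and 6.59 in replicate 2, below the 8.46 and 7.95 of all shared peaks. Over all peaks of the window, shared or not, the median signal value was 5.165 and 6.18, against 7.61 and 7.28 in the full lists. Their median −log10 p was 6.88 and 9.55, against 8.90 and 9.11 in the full lists. On chromosome 10 from 69.5 to 69.6 Mb all 9 replicate 1 peaks were shared. A further 6 windows, on chromosomes 1, 2, 5, 12 and 17, tied with 8 shared peaks each, and 2 of them were on chromosome 2.

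**Figure D3:**
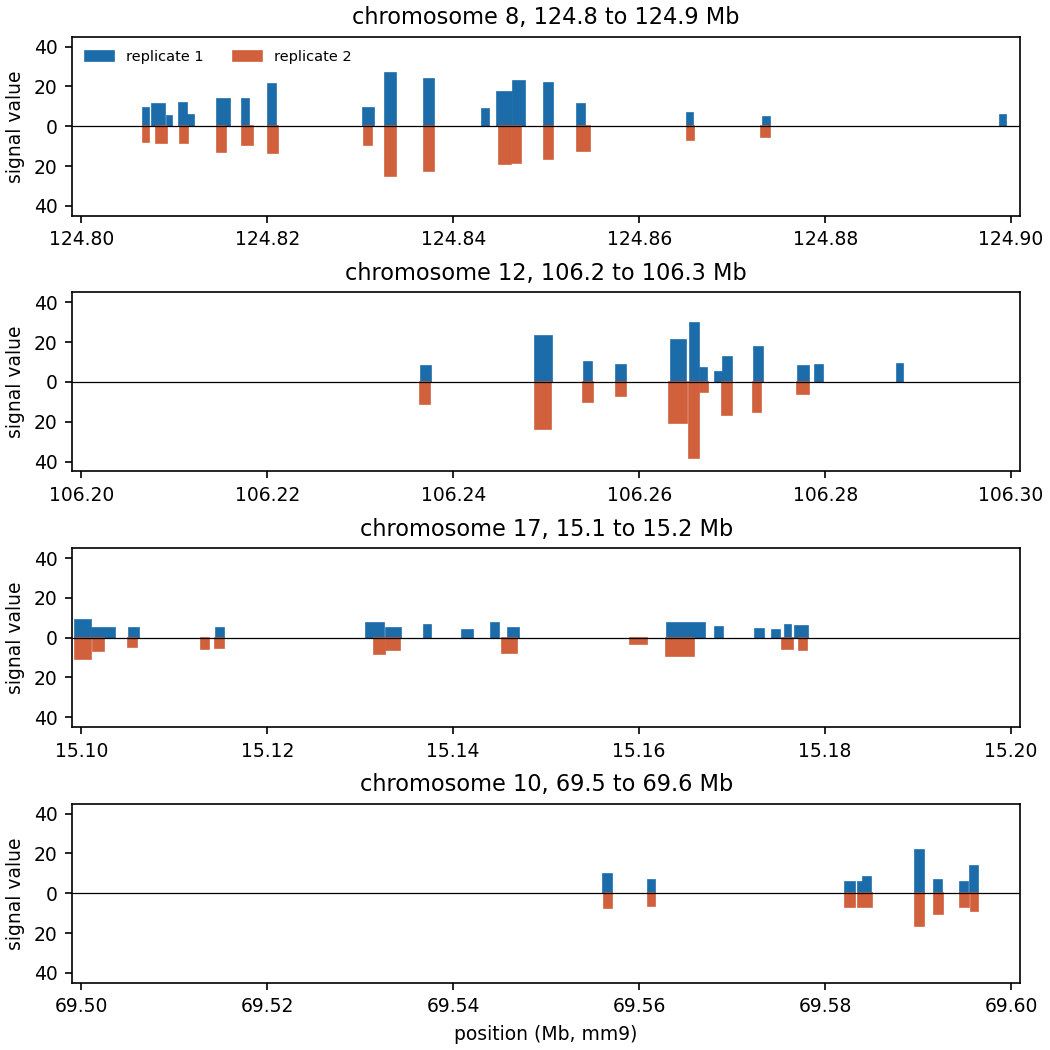
Peaks in the 4 windows of 100 kb with the most shared peaks. Each bar spans a peak's start and end (horizontal axis, position in Mb on mm9) and its height is the signal value, drawn upwards for replicate 1 and downwards for replicate 2. The chromosome 8 window holds 19 and 15 peaks, and the chromosome 17 window holds 16 and 12 with mostly lower signal values.

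Chromosomes differed in the density of GATA1 sites, and the samples gave like densities. Each of the 20 chromosomes had intervals of its share of peaks that overlapped between the lists. Density was highest on chromosome 12, at 5.36 peaks per Mb of spanned sequence in replicate 1 and 5.41 in replicate 2, and on chromosome 11, at 5.13 and 5.09. Of the chromosome 12 peaks, 287 of 624 and 286 of 629 lay between 70 and 90 Mb, a stretch chosen after its values were seen, and the rest of the chromosome had 3.50 and 3.56 peaks per Mb. Among the other autosomes it ranged down to 1.77 and 1.85 on chromosome 14. Chromosome X held 39 peaks in replicate 1, or 0.529% of the list (0.376 to 0.722%), and 34 in replicate 2, or 0.454% (0.314 to 0.633%). That is 0.251 and 0.218 peaks per Mb, against 3.07 and 3.12 over all autosomes. The share of replicate 1 peaks recovered in replicate 2 ranged from 65.7% on chromosome 13 to 76.1% on chromosome 8, and was 66.7% on X.

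**Figure D4:**
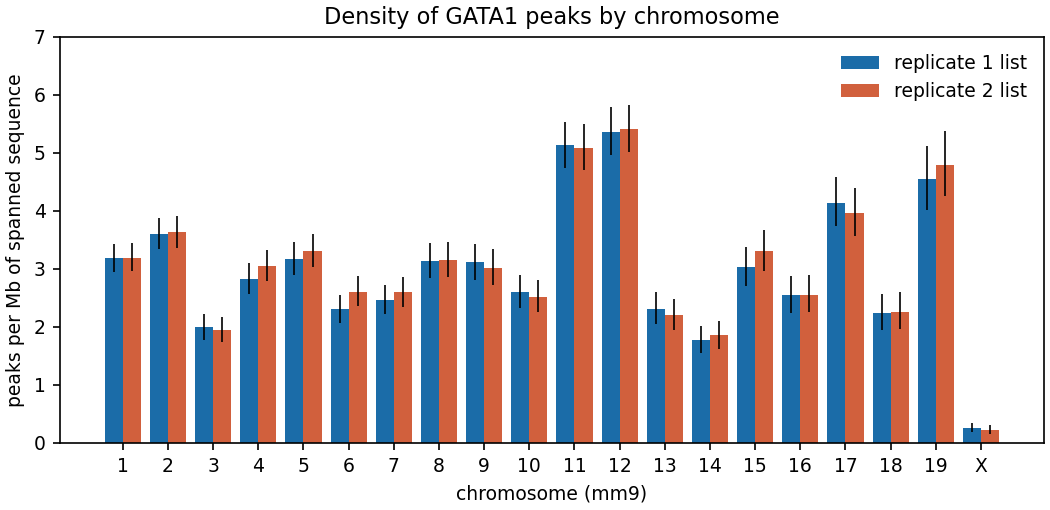
Peaks per Mb between the first and the last peak of each chromosome (vertical axis) for the replicate 1 and replicate 2 lists, with exact 95% binomial intervals of the chromosome's share of peaks scaled to density. Chromosome 12 has the highest density (5.36 and 5.41) and X the lowest (0.251 and 0.218).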

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

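The alternatives with −log10 p of 10 or more in both lists and without chromosome 12 were chosen after seeing the data. Shared peaks stayed far above shifted lists (permutation p = 0.001) under all 10 alternatives, with 66.4 to 74.2% of replicate 1 peaks and 65.3 to 70.9% of replicate 2 peaks shared. The Spearman rho of 0.69 for signal values moved outside its bootstrap interval under 3 of 5 alternatives. It was 0.66 for the stronger 50% of each list, 0.71 for −log10 p in place of the signal value and 0.63 for the middle 50% of widths. A list cut to part of its peaks can span a narrower range of values, which lowers a rank correlation by itself. The lower values therefore do not show poorer agreement of those peaks. The mean probability that a shared peak outranked an unshared one, 78.1% over the lists, was 77.6% with 50% reciprocal overlap, 81.0% on −log10 p and 77.9% without chromosome 12. Each of these lay beyond the SD between the lists (0.19 percentage points, n = 2), and none changed direction. An SD of 2 values is not the uncertainty of the probability. Against the bootstrap intervals of the lists (76.9 to 78.9% and 77.2 to 79.2%), 77.6% and 77.9% lay within both and 81.0% above both. The mean percentage of peaks with a neighbour within 10 kb, 41.1%, was above redistributed peaks under all 8 alternatives (permutation p = 0.001). It was 26.7% for the stronger 50% of peaks, 33.4% after merging peaks within 1 kb, and 40.4 to 41.8% when either list was left out. Leaving out a list gives the other list's own value reported above, so it adds no new test. The redistributed percentage depends on the number of peaks. It was 6.47% in the main setting, 3.31% for the stronger 50% and 6.02% after merging, so the lower 26.7% does not show weaker clustering of strong peaks. Of the other results, overlap, signal agreement and rank probability need both lists, so leaving out a replicate gave no value. The 2 tests on gene positions were not run, for lack of an mm9 annotation. No paired analysis was possible because peak lists were at hand for 1 group only. Sites below the deposited p limit of 1e-05 are not listed, so a site found in 1 list only may lie just under that limit in the other. When both lists were cut to their stronger 25%, 70.4% and 69.2% of the peaks kept were shared. A partner below the other list's cut does not count there, so these values are no measure of recovery in the full lists, which was 96.6% and 96.3% in the second strongest decile and 100% and 99.1% in the strongest.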

Other observations

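All tests in this part were chosen after the values they concern had been seen, and the explanations are hypotheses. Intervals of density ratios in this part treat peaks as independent counts. Since peaks clustered, these intervals are too narrow.

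GATA1 sites were crowded on chromosome 12 between 70 and 90 Mb. This stretch held 287 peaks in replicate 1 and 286 in replicate 2, 14.4 and 14.3 per Mb, which is 4.86 times (95% interval 4.31 to 5.47) and 4.76 times (4.22 to 5.36) the density of the other autosomes. The median signal value there was 6.77 and 6.67, against 7.61 and 7.28 on the other autosomes. Marginal calls near the threshold would leave no such excess among strong peaks, yet among peaks with −log10 p of 20 or more it was 4.56 times (3.24 to 6.26) in replicate 1 and 4.66 times (3.35 to 6.32) in replicate 2. The excess may also come from extra copies of the region in these cells. Extra copies that also raise the local background used for the signal value cannot be told apart from other sources, since no value decides. Of the signal values there, 82.6% lay on the common step described below in replicate 1 and 82.5% in replicate 2. The other autosomes had 74.8% and 74.4%, but they include the regions off the step. The stretches mostly on the step named below for chromosomes 1, 2, 7, 9 and 14 ranged from 79.8 to 91.4% in replicate 1 and from 82.0 to 93.3% in replicate 2. The median log2 signal at matched −log10 p on the chromosome 12 stretch was −0.0947 in replicate 1 and −0.0871 in replicate 2, against 0 on the other autosomes. This lowering is not particular to the stretch, with −0.0896 and −0.0738 over the rest of chromosome 12, which held 3.50 and 3.56 peaks per Mb. Extra copies absent from a control library, the number of genes in the region, and regulation by GATA1 stay open, and no biological explanation was tested.

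GATA1 sites were scarce on chromosome X. Its density was 0.0817 times that of the autosomes in replicate 1 (0.0580 to 0.112) and 0.0700 times in replicate 2 (0.0484 to 0.0979). Only weak peaks missing on X would leave the strong ones in place, but the ratio for peaks with −log10 p of 10 or more was 0.058 (0.030 to 0.102) in replicate 1 and 0.060 (0.032 to 0.103) in replicate 2. These ratios rest on 12 and 13 X peaks, and the cut lies close to the list medians of 8.90 and 9.11. They show only that the loss was not confined to peaks below that cut. A lower copy number of X in these cells could thin out the calls: against autosomal peaks with at least 2 times the signal value at the lower end of the list (5.07 in replicate 1 and 4.63 in replicate 2, reached by at least 95% of peaks), the X ratio was 0.344 (0.244 to 0.473) and 0.267 (0.185 to 0.375), and against those with at least 3 times it was 1.20 (0.843 to 1.66) and 0.931 (0.638 to 1.32). This comparison assumes that X otherwise had the autosomal density and that calls depended on signal value alone. Under these assumptions a 2-fold loss of signal value would leave more peaks on X than were found. A 3-fold loss would leave about as many as found. The lists are limited by p and not by signal value, and how far a lower dose reduces either is not known for these files. A dose effect, also one of 2-fold, therefore cannot be told apart from true scarcity of sites on X. Gene number and unmappable sequence were not tested.

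Most signal values fell on a regular grid, but few did in some regions. In replicate 1, 75.5% of the values were whole multiples of 0.423 within 0.006, where chance gives 2.84%, and in replicate 2, 75.1% were multiples of 0.331, where chance gives 3.62%. On chromosome 1 below 140 Mb only 11.6% (8.83 to 14.9%) and 11.3% (8.54 to 14.6%) of values lay on the step, and beyond 160 Mb 91.4% and 93.3% did. Peak strength does not account for this. In every quintile of signal value in replicate 1 the share on chromosome 1 was at most 31.0%, against at least 73.8% on the other autosomes, and in replicate 2 it was at most 43.8% against at least 72.5%. A raised local background over large regions, such as extra chromosome copies in the cells or in a control library common to both lists, is a candidate explanation. The relation was measured over the 199 windows of 10 Mb with at least 10 peaks in each list, so regions with few peaks are not covered. The share on the step in replicate 1 went with the signal at matched −log10 p in replicate 2 (Spearman rho 0.28, Pearson r 0.55, permutation p = 9.0e-05, Benjamini-Hochberg adjusted over 3 relations 9.0e-05). The reverse gave rho 0.32 (Pearson r 0.52, adjusted permutation p = 1.5e-05), although neighbouring windows are not independent. Not all values go with a raised background, since the stretch of chromosome 12 above had lower signal at matched −log10 p while on the step.

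Under 50% of values lay on the step in both lists in 29 of the 199 windows, 12 on chromosome 1, 7 on chromosome 7 and the other 10 on chromosomes 2, 3, 9, 12, 14 and 17. On chromosome 7 the share on the step was 7.69% and 6.94% below 90 Mb and 79.8% and 82.0% beyond 100 Mb. On chromosome 2 it was 88.1% and 86.1% below 140 Mb and 19.6% and 22.5% beyond 160 Mb. On chromosome 9 it was 88.2% and 86.9% below 110 Mb and 7.89% and 13.5% beyond. On chromosome 14 it was 82.2% and 82.0% below 110 Mb and 22.2% and 21.2% beyond. Single windows of this kind were on chromosome 3 from 90 to 100 Mb (22.4% and 22.2%), chromosome 12 from 20 to 30 Mb (20.8% and 14.7%) and chromosome 17 from 10 to 20 Mb (40.6% and 46.9%). The last held 32 peaks in each list, of which 16 and 12 lay between 15.1 and 15.2 Mb, with 0 on the step. Its low share thus rests largely on that 100 kb locus and does not show a large region off the step. Over the 199 windows the lists' shares had a Spearman rho of 0.83 and a Pearson r of 0.97 (adjusted permutation p = 1.5e-05, close to the smallest that 100000 resamples give). On X, 100% and 97.1% of values lay on the step. In the dense chromosome 17 window from 15.1 to 15.2 Mb, 0 of 16 values in replicate 1 and 0 of 12 in replicate 2 lay on the step. In the other dense windows it was 9 of 19 and 8 of 15 (chromosome 8), 12 of 13 and 9 of 10 (chromosome 12, 106.2 to 106.3 Mb), and 8 of 9 and 7 of 8 (chromosome 10). The median log2 signal at matched −log10 p in the chromosome 17 window was −0.414 in replicate 1 and −0.323 in replicate 2 relative to all peaks of the list, so its low signal values do not show weak sites by themselves.

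The −log10 p column holds the value 310 for 1 peak in replicate 1 and for 4 peaks in replicate 2, and 2 peaks of replicate 1 lie above it, at 316.4 and 314.1, so the order of the strongest peaks by −log10 p is not resolved at that level.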
